A study of Mus musculus with 11 samples.

How the data were processed

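RNA of sorted mouse effector T cells was measured on 11 arrays in 4 groups. The series design text names the Affymetrix Mouse Exon 1.0 ST array. The labels' protocols name a labelling kit made for 3' expression arrays, and the difference between these statements could not be settled from the sources used here. Per the submitters' processing notes the tools were Partek and RMA with the mm9 build, without versions. The deposited values are on a log2 scale, which was checked on their range, and RMA as published includes background correction, quantile normalization between arrays and a summary of the probes of each probe set. No centring of the probe sets was found. The summary level and any filter on probe sets are not given in the sources used here, and scanner files were not analysed here.

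The deposited table held 16673 probe sets, and all of them were tested. In the array annotation, 14970 carried 1 gene symbol, 1019 carried several and 684 carried none. Of the probe sets with 1 symbol, 14920 were matched to a reference gene by their Entrez identifier, and 14835 genes could be named. For 134 genes with several probe sets, the one with the highest mean over all arrays stood for the gene. Genomic positions are not given, because the processing notes name mm9 while the reference annotation used here is of a later build. Quantile normalization would make the distributions of the arrays nearly alike, yet the SD of the deposited values ran from 1.54 to 2.06 between arrays. This difference was left in the values, and its effect is reported beside the results. For arrays, the number of arrays limits the precision.

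Groups were compared with limma 3.58.1 under R 4.3.3. A single linear model with 1 coefficient per group was fitted to all 11 arrays, so that the groups of 2 or 3 arrays shared 1 estimate of spread (7 residual and 3.80 prior degrees of freedom). Values are log2 differences with the moderated standard error (SE), and p-values are two-sided and adjusted by Benjamini-Hochberg over all probe sets of a comparison. The threshold was an adjusted p under 0.05, and counts were also taken at a change of at least 1 on the log2 scale. The 5 comparisons, the tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from the additions named here and in the closing part. The labels do not say that a replicate number marks a shared preparation, so no replicate block was fitted in the results reported. Same-number arrays of different groups were compared after removing group means, and 8 of 15 pairs had a correlation across genes above 0.1 (median 0.174 against -0.05 for other pairs). For wild-type CD4+CD8- with Thpok-deficient CD4+CD8+ cells all 3 same-number pairs exceeded 0.1 (0.650, 0.429 and 0.724), so the numbers were read as pairs for that comparison alone, from the data and not from the labels. Both arrays numbered 3 there have a narrow signal range, which raises these correlations whether or not a preparation was shared, and wild-type replicate 2 correlated more with Thpok-deficient replicate 1 (0.524). The block also treats 3 numbers as separate although the labels give only 2 distinct cell preparations, so the calls it adds rest on an assumption. It was fitted over all groups and is given beside that result and elsewhere only among the alternatives.

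In total 23 gene lists were fixed, with 260 of 336 entries measured. They cover the CD8 and CD4 helper lineages, cytotoxic granules, NK-type receptors, helper programs (Th1, Th2, Th17, Treg and Tfh), naive and memory genes, inhibitory receptors, lineage transcription factors, cytokine receptors, chemokine receptors with adhesion molecules, interferon response, cell cycle, glycolysis and apoptosis. A further 5 lists hold markers of B cells, myeloid cells, NK cells, gamma-delta T cells and erythroid cells. Each list was compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. The fry test was run beside it. It asks whether the genes of a list move one way on balance, and it does not compare them with other genes. Counts "adjusted over the list alone" use only the genes of the list. The CD8 lineage list holds Cd8a and Cd8b1 and the CD4 helper list holds Cd4, which are genes of the sort markers. The lists were not tested without them.

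Genes were named by a fixed rule from probe sets with 1 symbol. The rule takes up to 10 largest rises and 10 largest falls past the threshold with no overlap between the arrays of the groups, leaving out predicted genes, pseudogenes and antigen receptor segments. It adds 13 genes in every comparison (Zbtb7b, Zbtb7a, Cd4, Cd8a, Cd8b1, Runx3, Eomes, Tbx21, Gata3, Ifng, Prf1, Gzmb and Cd40lg), up to 4 members of a list by size of change with those past the threshold first, and for each overlap the 5 genes with the largest smaller change.

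A CD8 signature was made from probe sets past the threshold with a change of at least 1 between wild-type CD8 and wild-type CD4+CD8- cells. The score of an array is the mean log2 value of the probe sets higher in CD8 cells minus that of the probe sets lower in CD8 cells. The difference between the Thpok-deficient subsets was tested by an exact permutation test (two-sided, 3 against 3, smallest possible p 0.1), since the means of neither subset entered the contrast that chose the signature, although their arrays share in the spread of the model and so in which probe sets pass. Groups compared with wild-type CD4+CD8- cells share those arrays with the signature, so 100 simulations were run to show what sharing alone produces. For the score, CD8 cells kept their change and the Thpok-deficient groups had none. For the overlap and the correlations, no group had a change. Noise was drawn independently for each gene.

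The model was tested on simulated data with the model's spread of each gene, equal in all arrays and independent between genes. The real arrays differ in noise, from 0.47 to 1.80 times their common level, so the shares below describe the model under its own assumptions. For Thpok-deficient against wild-type CD4+CD8- cells, changes of 1, 2 and 3 on the log2 scale were recovered in 34.8%, 94.0% and 98.5% of cases, with 4.40% false calls. For CD8 against CD4+CD8- cells the shares were 27.3%, 89.6% and 100%, with 5.23% false calls. In each of these comparisons 3 of 3 shifted lists of randomly drawn genes were found and 0 others, which does not cover lists whose genes vary together. Alternatives were a replicate block, only the 2 groups compared, a filter at the 30th percentile of mean signal, a further quantile normalization, median centring, a trended robust prior, no moderation, array weights (estimated gene by gene, because the usual REML estimate did not converge), 1 probe set per gene, the mean of the probe sets of a gene, an adjusted p under 0.01, other sizes of change for the signature (1.5-fold and 4-fold), the signature without the sort markers and leaving out each array. A fit without 2 arrays of narrow signal range was added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.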

Results

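Expression was compared in T cells that had become Th1-type effectors in culture. Naive CD44-low T cells from mouse spleen were activated with antibodies to CD3 (1 µg/ml) and CD28 (3 µg/ml) beside irradiated T-depleted splenocytes as antigen-presenting cells. The medium held IL-2 (50 U/ml), IL-12 (10 ng/ml) and an antibody to IL-4 (10 µg/ml), which steer CD4 T cells toward the Th1 fate, and cells were sorted on day 4. Wild-type cultures gave CD4+CD8- cells (3 arrays) and CD4-CD8+ cells (2 arrays, called CD8 cells here). Cultures of Thpok-deficient CD4 T cells, in which a CD2-driven Cre recombinase deletes floxed alleles, gave CD4+CD8- cells (3 arrays) and CD4+CD8+ cells (3 arrays). Thpok, encoded by Zbtb7b, is a zinc finger transcription factor that commits developing T cells to the CD4 lineage and restrains CD8 lineage genes. The replicates came from 2 distinct cell preparations and the labels do not say which array came from which, so the p-values may partly measure technical spread. Values are deposited log2 intensities with SD and number of arrays, and changes are log2 differences with SE.

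Replicate 3 of the wild-type CD4+CD8- cells and replicate 3 of the Thpok-deficient CD4+CD8+ cells stood apart from the other 9 arrays. Their values had an SD of 1.54 and 1.70 over all probe sets, against 1.94 to 2.06 in the others. Olfactory receptor genes, counted here together with vomeronasal and trace amine receptor genes, serve smell and mark background in T cells. They had medians of 4.79 and 4.21, against 3.26 to 3.68. The correlation across genes within a group ran from 0.904 to 0.983 in wild-type CD4+CD8- cells, 0.937 to 0.979 in Thpok-deficient CD4+CD8+ cells and 0.988 to 0.992 in Thpok-deficient CD4+CD8- cells, and was 0.969 for the CD8 pair. Each count was therefore repeated on the other 9 arrays, a choice made after seeing the data.

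**Figure D1:**
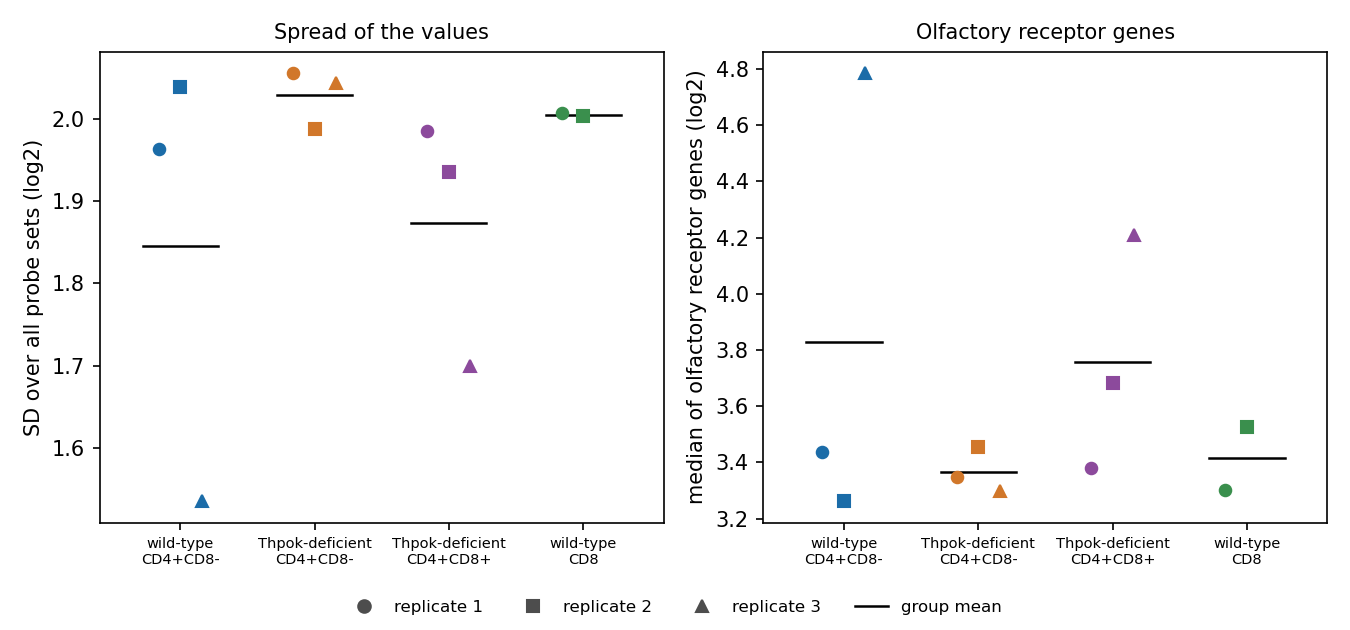
Spread of the deposited values of each array (left, SD over all probe sets on the log2 scale) and median signal of olfactory receptor genes (right, log2, vomeronasal and trace amine receptors included), by group. Points are single arrays and lines are group means. Replicate 3 of the wild-type CD4+CD8- cells (SD 1.54) and of the Thpok-deficient CD4+CD8+ cells (SD 1.70) lie below all other arrays on the left and above them on the right.

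The gene that encodes Thpok, Zbtb7b (probe set 6906834), read 8.43 ± 0.35 (SD, n = 3) in wild-type CD4+CD8- cells. It read 6.90 ± 0.23 (n = 3) in Thpok-deficient CD4+CD8- cells, 6.69 ± 0.36 (n = 3) in Thpok-deficient CD4+CD8+ cells and 7.06 ± 0.24 (n = 2) in CD8 cells. The change from wild-type CD4+CD8- cells was -1.73 ± 0.25 in the CD4+CD8+ subset (limma adjusted p = 0.0246), and Zbtb7b fell there. In the Thpok-deficient CD4+CD8- cells it was -1.53 ± 0.25 (adjusted p = 0.0562) and in CD8 cells -1.37 ± 0.28 (adjusted p = 0.0653), which did not pass the threshold. On the 9 arrays these values were -1.72 (adjusted p = 0.0326) and -1.57 (adjusted p = 0.0213). The position of the probes relative to the deleted segment is not given in the sources used here. Cd4 read 10.28 ± 0.63, 9.64 ± 0.50 and 9.76 ± 0.56 in the 3 CD4-bearing groups (n = 3 each) and 4.81 ± 0.54 (n = 2) in CD8 cells. Cd8a (probe set 6946920) read 5.14 ± 0.88 in wild-type CD4+CD8- cells, 6.97 ± 0.55 in Thpok-deficient CD4+CD8- cells, 9.91 ± 0.32 in Thpok-deficient CD4+CD8+ cells (n = 3 each) and 11.67 ± 0.16 (n = 2) in CD8 cells.

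**Figure D2:**
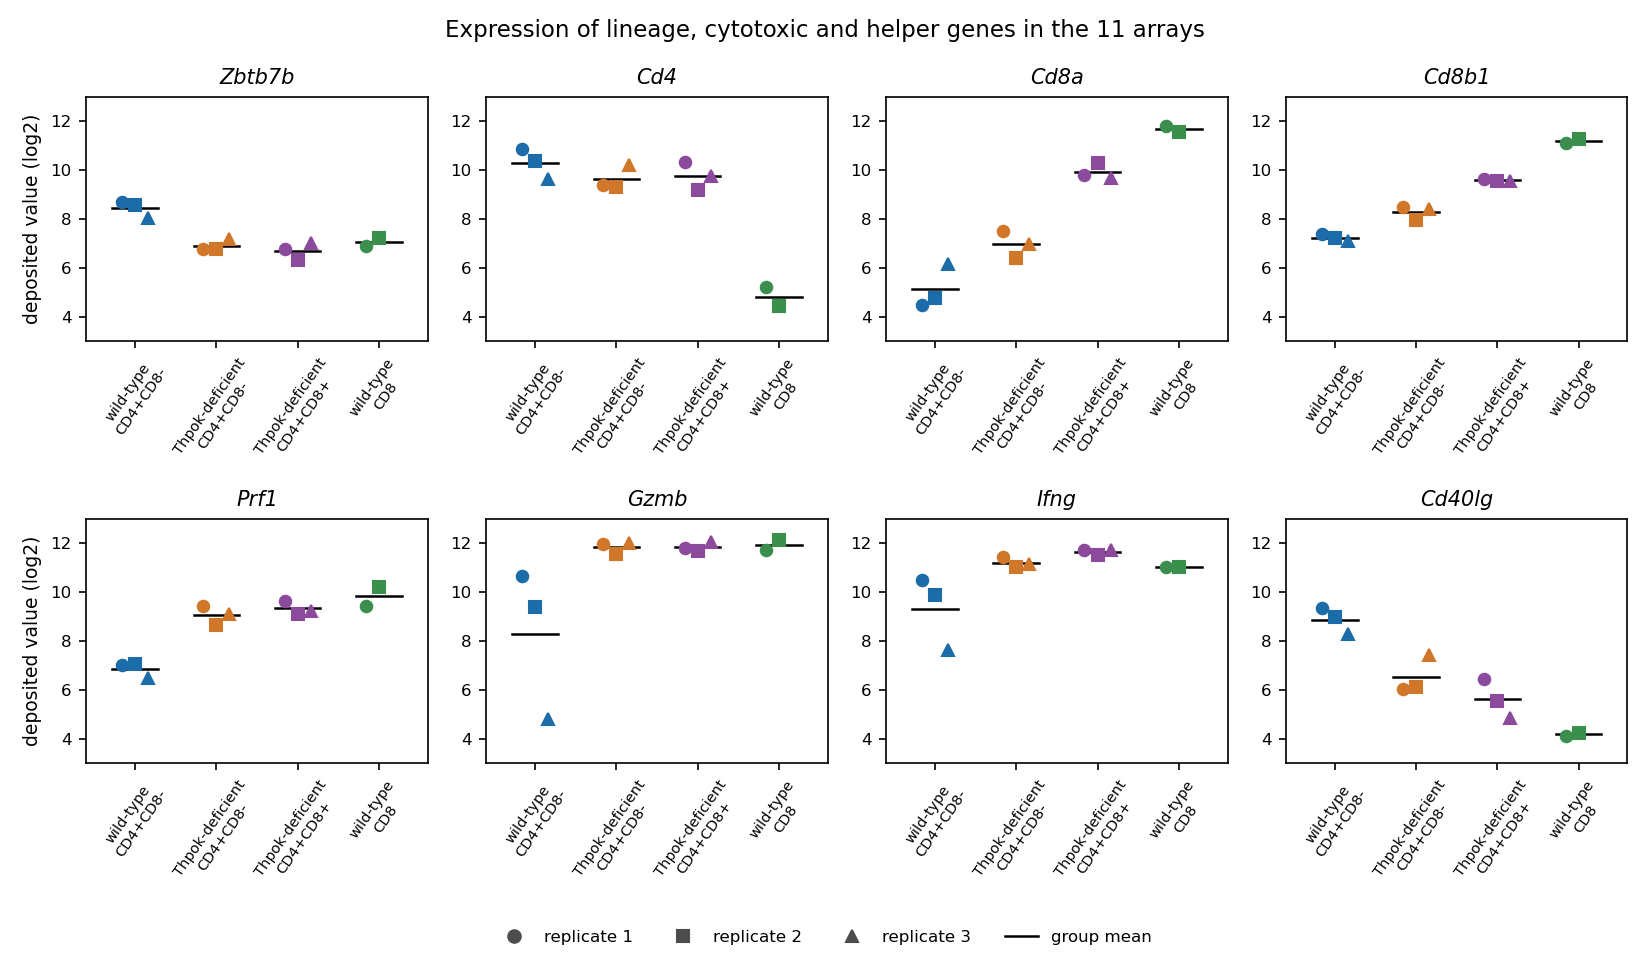
Deposited log2 values of 8 genes in the 11 arrays; symbols mark the replicates of 4 sorted groups and lines are group means. Cd8a and Cd8b1 step up from wild-type CD4+CD8- cells (means 5.14 and 7.23) through both Thpok-deficient subsets to CD8 cells (11.67 and 11.18), and wild-type CD4+CD8- replicate 3 is low for Gzmb (4.83) and Ifng (7.63).

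Wild-type CD8 and CD4+CD8- effectors give the lineage difference beside which Thpok-deficient cells can be placed. CD8 cells had more mRNA for the CD8 chains, with Cd8a higher by 6.53 ± 0.46 and Cd8b1 by 3.95 ± 0.20 (n = 2 and 3). Like Cd4, these are genes of the sort markers, so their differences were set by the sort. The killing proteins granzyme K and perforin were also higher, with Gzmk at 3.19 ± 0.38 and Prf1 at 2.97 ± 0.31. Il10, which encodes an immunosuppressive cytokine, rose by 3.78 ± 0.62 and Tnfrsf9, the costimulatory receptor 4-1BB, by 3.31 ± 0.42. Cd4 fell by 5.47 (SE 0.44) and Cd40lg, the CD40 ligand through which helper cells signal to B cells, fell by 4.68 (SE 0.51). Gata3, a transcription factor of CD4 and Th2 cells, fell from 9.39 ± 0.50 to 7.39 ± 0.62 (SD), Cd5 fell by 1.36 (SE 0.18) and Klf2, a regulator of T cell trafficking, fell by 1.93 (SE 0.33).

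Of 16673 probe sets, 50 were higher and 39 lower in CD8 cells (limma, adjusted p under 0.05), and 49 and 39 of these changed by at least 1. The further named rises were P2rx3, an ATP-gated ion channel (3.38), Zbtb32, a zinc finger repressor of the Thpok family (3.35), Jaml, an adhesion molecule (5.66-fold), and Usp11, a deubiquitinase (2.40). The further named falls were Amigo2 (-3.13), Tnfrsf25 (-3.02), the neuropeptide receptor Vipr1 (-3.01), Itih5 (-2.81), Tmem64 (-2.79), Klf3 (-2.63), Nsg2 (-2.56) and the Toll-like receptor Tlr1 (-2.47). Adjusted p-values of the named genes past the threshold ran from 1.55e-05 for Cd8b1 to 0.0349 for Klf2. A further quantile normalization gave 93 higher and 147 lower, and the 9 arrays gave 122 and 146, with 82 of the 89 probe sets called again and P2rx3 no longer called (adjusted p = 0.0657). The count was 8 without CD8 replicate 2, 44 without CD8 replicate 1 and 47 without wild-type CD4+CD8- replicate 2.

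In the same comparison 7 of the 23 gene lists shifted. CD8 lineage genes were higher in 9 of 11 members with 3 called and 5 adjusted over the list alone (median 0.82, adjusted p = 4.12e-09), and this list alone held with an estimated correlation (adjusted p = 0.0122), though not on the 9 arrays (0.0816). Cytotoxic genes were higher in all 14 members, of which Gzmk and Prf1 passed the test and 7 did adjusted over the list alone. Their median change was 1.32 (adjusted p = 1.25e-10, and adjusted p = 0.0927 with an estimated correlation), with values of 3.63 ± 1.23 for Gzmb and 2.12 ± 0.51 for Gzma. Wild-type CD4+CD8- replicate 3 read 4.83 for Gzmb, against 10.68 and 9.40 in replicates 1 and 2, which enlarges that change. CD4 helper genes were lower in 9 of 11 with 4 called and 6 adjusted over the list alone (median -1.36, adjusted p = 4.82e-08, and adjusted p = 0.0927 with an estimated correlation). Naive and memory genes were lower in 9 of 10 with 1 called and 4 adjusted over the list alone (median -0.48, adjusted p = 2.95e-05, and adjusted p = 0.0927 with an estimated correlation), and Ccr7, a lymph node homing receptor, stood at -1.68. Tfh genes were lower in 8 of 10 with 0 called and 1 higher and 4 lower adjusted over the list alone (median -0.74, adjusted p = 0.0396, and adjusted p = 0.314 with an estimated correlation), with the inhibitory receptor Btla at -1.97 and Slamf6 at -1.48. This list call ended with the filter on mean signal, and without wild-type CD4+CD8- replicate 2 or CD8 replicate 1. Cell cycle genes were higher in 20 of 20 members with 0 called and 10 adjusted over the list alone (median 1.46, adjusted p = 2.50e-12, and adjusted p = 0.211 with an estimated correlation), Bub1 at 2.06 and Ccna2 at 1.91. Glycolysis genes were higher in 8 of 9 members with 0 called and 0 adjusted over the list alone (median 0.81, adjusted p = 0.000239, and adjusted p = 0.313 with an estimated correlation), Hk2 at 1.71 and Pfkp at 1.41. Without the 2 arrays of narrow range the medians were 0.83 for cytotoxic, 0.83 for cell cycle and 0.39 for glycolysis genes, and 0 cell cycle genes passed adjusted over the list alone. NK-type receptors (median 0.32, adjusted p = 0.0169), lineage transcription factors (-0.31, 0.0119), cytokine receptors (-0.50, 0.0121) and chemokine receptors with adhesion molecules (-0.21, 0.0121) were called there in addition, and none of these with an estimated correlation (adjusted p = 0.144 to 0.248).

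Thpok-deficient and wild-type CD4+CD8- cells were compared to ask what loss of Thpok changes in cells that keep this surface phenotype. The Thpok-deficient cells had more mRNA for perforin and granzyme K, with Prf1 higher by 2.22 ± 0.28 and Gzmk by 2.49 ± 0.34 (n = 3 and 3). P2rx3 rose by 3.73 ± 0.52 and Zbtb32 by 3.44 ± 0.28, from 6.99 ± 0.11 to 10.44 ± 0.33 (adjusted p = 0.00200). Further rises were Slbp, which binds histone mRNA (2.28), Usp11 (2.13), the acid-sensing receptor Gpr65 (1.99), Nt5dc2 (1.79), Slc7a1, a transporter of cationic amino acids (1.47), and the chromatin protein L3mbtl2 (1.08). Amigo2 fell by 2.69 (SE 0.25), Tspan32, a T cell tetraspanin, fell by 2.01 (SE 0.26) and Sorcs2 fell by 1.26 (SE 0.18).

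In total 11 probe sets were higher and 3 lower (limma), all by at least 1, with adjusted p-values of the named genes from 0.00200 for Zbtb32 to 0.0446 for Slc7a1. Several genes of the CD8 and helper lineages had values that did not pass the threshold. Among these were Il10 at 3.20 ± 0.56 (adjusted p = 0.0600), Tnfrsf9 at 2.32 ± 0.38 (0.0562), Cd8a at 1.83 ± 0.41 (0.138), Cd8b1 at 1.06 ± 0.18 (0.0593), Cd40lg at -2.33 ± 0.46 (0.103) and Gata3 at -0.79 ± 0.29 (0.359). Gzmb stood at 3.53 ± 1.10 (0.249) and Ifng, the main Th1 cytokine, at 1.88 ± 0.55 (0.230), and wild-type CD4+CD8- replicate 3 read 4.83 and 7.63 for these genes against at least 9.40 and 9.88 in the other wild-type CD4+CD8- arrays. The Th1 regulator Tbx21 stood at 0.44 ± 0.22, Eomes, a regulator of CD8 effectors, at 0.64 ± 0.27, Runx3, which establishes the CD8 lineage, at 0.30 ± 0.30, Cd4 at -0.65 ± 0.40 and Zbtb7a, a close relative of Zbtb7b, at 0.14 ± 0.27.

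A further quantile normalization called 9 higher and 8 lower, and the 9 arrays called 18 higher and 21 lower. On the 9 arrays 10 of the 14 probe sets were called again, P2rx3, Slbp, Prf1 and Slc7a1 were not (adjusted p = 0.0564 to 0.0793), and Cd8a was called (2.33, adjusted p = 0.0424). The count was 2 without any 1 of the Thpok-deficient CD4+CD8- arrays, 35 without wild-type CD4+CD8- replicate 1 and 25 without replicate 3. The median change of all probe sets was -0.15 here, -0.14 for CD8 cells and 0.11 between the Thpok-deficient subsets, and the named changes can be read against these shifts.

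In the same comparison 8 of 23 lists shifted, and 1 held with an estimated correlation, the CD8 lineage genes (median 0.60, adjusted p = 7.55e-07, estimated 0.0299, and 0.106 on the 9 arrays). In that list 10 of 11 members were positive, 0 were called and 4 were higher adjusted over the list alone, with Cd160 at 1.74 beside Tnfrsf9, Cd8a and Cd8b1. Cytotoxic genes were higher in all 14 members, with 2 called and 5 adjusted over the list alone (median 1.14, adjusted p = 9.72e-11, and adjusted p = 0.179 with an estimated correlation), Gzma at 2.32. Th1 genes were higher in 15 of 18 with 0 called and 0 adjusted over the list alone (median 0.36, adjusted p = 0.000857, and adjusted p = 0.212 with an estimated correlation), the inhibitory receptor Havcr2 at 1.92 and the chemokine Ccl3 at 1.82. Inhibitory receptors went both ways, with 5 of 8 higher, 0 called, and 4 higher and 2 lower adjusted over the list alone (median 1.23, adjusted p = 0.0241, and adjusted p = 0.194 with an estimated correlation), Pdcd1 at 1.56. Cell cycle genes were higher in 20 of 20, with 0 called and 20 adjusted over the list alone (median 1.62, adjusted p = 8.97e-19, and adjusted p = 0.194 with an estimated correlation), Bub1 at 2.17 and Ccna2 at 2.15. Glycolysis genes were higher in 9 of 9 with 0 called and 0 adjusted over the list alone (median 0.60, adjusted p = 0.00307, and adjusted p = 0.409 with an estimated correlation), Hk2 at 1.16 and Tpi1 at 0.86, and this call ended on the 9 arrays (median 0.17, adjusted p = 0.269). CD4 helper genes were lower in 9 of 11 with 0 called and 3 adjusted over the list alone (median -0.65, adjusted p = 0.00412, and adjusted p = 0.299 with an estimated correlation), Tnfsf8 at -1.96. Naive and memory genes were lower in 9 of 10 with 0 called and 3 adjusted over the list alone (median -0.35, adjusted p = 0.00560, and adjusted p = 0.194 with an estimated correlation), Ccr7 at -1.52, the egress receptor S1pr1 at -1.32 and Klf2 at -1.16. Cell cycle, cytotoxic and glycolysis genes all had their lowest list mean in wild-type CD4+CD8- replicate 3 (6.08, 6.91 and 7.93), and cell cycle and cytotoxic genes kept medians of 0.98 and 0.60 on the 9 arrays and inhibitory receptors of 0.62. NK-type receptors (median 0.21, adjusted p = 0.00540) and lineage transcription factors (-0.17, 0.0341) were called there in addition, but not with an estimated correlation (adjusted p = 0.139 and 0.375). A further quantile normalization gave medians of 0.19 for Th1 and 0.39 for glycolysis genes, and median centring gave -0.22 for naive and memory genes. The helper list was not called without wild-type CD4+CD8- replicate 2, and the naive and memory list and inhibitory receptors were called neither without replicate 1 nor without replicate 2.

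Thpok-deficient CD4+CD8+ cells were compared with the same wild-type cells to show what differs where CD8 appears beside CD4. Cd8a rose by 4.77 ± 0.41 and Cd8b1 by 2.34 ± 0.18 (n = 3 and 3), and both are genes of the marker by which the groups were sorted. Perforin and granzyme K mRNA rose as well, with Prf1 at 2.47 ± 0.28 and Gzmk at 2.58 ± 0.34, and so did Il10 (3.65 ± 0.56), Tnfrsf9 (2.58 ± 0.38) and Cd160 (2.04 ± 0.30). Cd40lg fell by 3.24 (SE 0.46) and Ccr7 fell by 1.95 (SE 0.31), beside Zbtb7b. The largest other rises were Zbtb32 (12.2-fold), P2rx3 (3.58), the transporter Slc43a3 (2.08) and Usp11 (2.07), and the other named falls were Amigo2 (-2.52), Tspan32 (-2.21), Klf3 (-2.16), Pde2a (from a mean of 10.26 to 8.27), Vipr1 (-1.71), Tlr1 (-1.70) and Tmem71 (-1.47).

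In total 23 probe sets were higher and 11 lower (limma), 22 and 11 of them by at least 1, with adjusted p-values of the named genes from 0.000629 for Zbtb32 to 0.0479 for Slc43a3. Values that did not pass the threshold were Ifng at 2.32 ± 0.55 (adjusted p = 0.138), Gzmb at 3.54 ± 1.10, Gata3 at -0.85 ± 0.29, Tbx21 at 0.54 ± 0.22, Eomes at 0.55 ± 0.27, Runx3 at 0.40 ± 0.30, Cd4 at -0.52 ± 0.40 and Zbtb7a at 0.26 ± 0.27. The low readings of wild-type CD4+CD8- replicate 3 (4.83 for Gzmb and 7.63 for Ifng, against at least 9.40 and 9.88 in the other wild-type CD4+CD8- arrays) enlarge these 2 changes. A further quantile normalization called 60 higher and 86 lower, median centring 9 and 2, and the 9 arrays 13 and 15. With the replicate number as a block, 56 were higher and 30 lower, and Ccl3 (adjusted p = 0.0391), Btla (0.0425), S1pr1 (0.0314), Klf2 (0.0427) and Bub1 (0.0445) were called beside all genes named above as called. On the 9 arrays 13 of the 34 probe sets were called again, among them Cd8a, Cd8b1, Zbtb32, Usp11, Amigo2, Tspan32, Pde2a and Zbtb7b, while the other named genes had adjusted p-values from 0.0589 to 0.142. Leaving out single arrays gave counts from 4 without Thpok-deficient CD4+CD8+ replicate 3 to 70 without wild-type CD4+CD8- replicate 1. It gave 7 and 20 without Thpok-deficient CD4+CD8+ replicates 2 and 1, and 20 and 58 without wild-type CD4+CD8- replicates 2 and 3.

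Of the 23 lists 11 shifted, and 2 of these held with an estimated correlation on 11 arrays but not on the 9 arrays (adjusted p = 0.0799 for each). They were CD8 lineage genes, higher in 10 of 11 with 4 called and 5 adjusted over the list alone (median 1.12, adjusted p = 2.43e-12, estimated 0.00438), and naive and memory genes, lower in 10 of 10 with 1 called and 4 adjusted over the list alone (median -0.35, adjusted p = 5.59e-07, estimated 0.0454), S1pr1 at -1.98 and Klf2 at -1.18. Cytotoxic genes were higher in all 14 members with 2 called and 6 adjusted over the list alone (median 1.12, adjusted p = 1.10e-11, and adjusted p = 0.102 with an estimated correlation), Gzma at 1.89. CD4 helper genes were lower in 10 of 11 with Cd40lg and Zbtb7b called and 4 adjusted over the list alone (median -0.52, adjusted p = 2.28e-06, and adjusted p = 0.130 with an estimated correlation), Tnfsf8 at -2.50. Cell cycle genes were higher in 20 of 20 with 0 called and 19 adjusted over the list alone (median 1.61, adjusted p = 3.31e-20, and adjusted p = 0.130 with an estimated correlation), Ccna2 at 2.39 and Bub1 at 2.06. NK-type receptors were higher in 8 of 10 with Cd160 alone called (median 0.20, adjusted p = 0.0236, and adjusted p = 0.220 with an estimated correlation), Klrd1 at 1.69. Th1 genes went both ways, with 11 of 18 higher, 0 called and 4 adjusted over the list alone (median 0.33, adjusted p = 0.00779, and adjusted p = 0.220 with an estimated correlation), Ccl3 at 3.07 and Havcr2 at 2.30. Inhibitory receptors also went both ways, with 6 of 8 higher, Cd160 called, and 4 higher and 2 lower adjusted over the list alone (median 1.23, adjusted p = 0.0249, and adjusted p = 0.130 with an estimated correlation). Tfh genes were lower in 8 of 10 with 0 called and 1 higher and 3 lower adjusted over the list alone (median -0.67, adjusted p = 0.00796, and adjusted p = 0.220 with an estimated correlation), Btla at -1.61 and Slamf6 at -1.40. Among lineage transcription factors 9 of 15 were lower, with only Zbtb7b, the deleted gene, called (median -0.19, adjusted p = 0.0194, and adjusted p = 0.282 with an estimated correlation). Among chemokine receptors and adhesion molecules 12 of 20 were lower, with Ccr7 alone called (median -0.07, adjusted p = 0.0236, and adjusted p = 0.130 with an estimated correlation). On the 9 arrays the calls of NK-type receptors (adjusted p = 0.0580), Th1 genes (median 0.09, adjusted p = 0.379) and inhibitory receptors (0.68, 0.164) ended, the medians of cytotoxic and CD8 lineage genes were 0.50 and 0.69, and cytokine receptors were called (-0.37, adjusted p = 0.0143, and adjusted p = 0.273 with an estimated correlation). With the replicate block the call of inhibitory receptors ended (adjusted p = 0.0719) and glycolysis genes were called (median 0.40, adjusted p = 0.0413), but without the block they had an adjusted p = 0.599 with an estimated correlation, and their median on the 9 arrays was 0.10. A further quantile normalization gave medians of 0.21 for Th1 genes, -0.38 for lineage transcription factors and -0.13 for chemokine receptors with adhesion molecules. The calls of NK-type receptors, Tfh genes, lineage transcription factors and chemokine receptors with adhesion molecules ended without wild-type CD4+CD8- replicate 2 and without Thpok-deficient CD4+CD8+ replicate 3. All of these but Tfh genes also ended without wild-type CD4+CD8- replicate 1. Calls of NK-type receptors, Th1 genes and inhibitory receptors ended without wild-type CD4+CD8- replicate 3. The filter on mean signal ended those of NK-type receptors and of chemokine receptors with adhesion molecules.

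**Figure D3:**
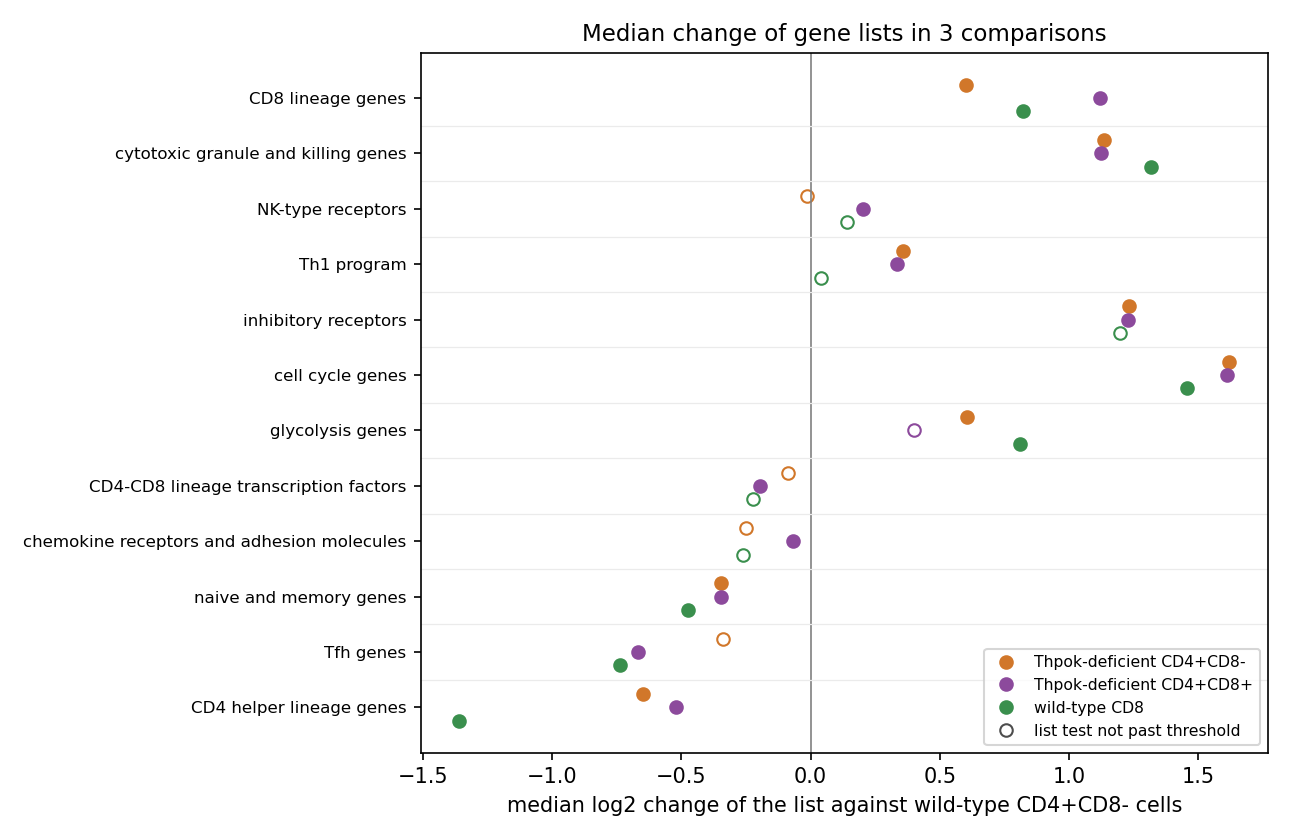
Median log2 change of 12 gene lists against wild-type CD4+CD8- cells in Thpok-deficient CD4+CD8- cells, Thpok-deficient CD4+CD8+ cells and wild-type CD8 cells; filled points passed the camera test with a preset correlation (adjusted p under 0.05) and open points did not. Cell cycle genes have the largest positive medians (1.46 to 1.62) and CD4 helper genes in CD8 cells the largest negative median (-1.36).

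The genes called in the Thpok-deficient cells were then set beside the lineage difference. Of the 14 probe sets called in Thpok-deficient CD4+CD8- cells, 9 were also higher and 3 also lower in CD8 cells, led by P2rx3, Zbtb32, Amigo2, Gzmk and Prf1. Independent calls would give 0.0330 and 0.00702. Of the 34 called in Thpok-deficient CD4+CD8+ cells, 19 were also higher and 9 also lower in CD8 cells, led by Cd8a, Il10, P2rx3, Zbtb32 and Cd40lg. Independent calls would give 0.0690 and 0.0257. The Thpok-deficient subsets shared 10 higher and 2 lower calls, led by P2rx3, Zbtb32, Amigo2, Gzmk and Prf1, against 0.0152 and 0.00198. No gene was called in opposite directions in any of these 3 pairs. The 3 comparisons share the wild-type CD4+CD8- arrays. Where no group was changed, CD8 cells included, simulated groups shared at most 1 call in any pair. Such groups have almost no calls to share, so this count does not show what sharing gives beside the real lineage difference. The correlations of the log2 changes across genes, which are not independent replicates, were 0.841, 0.725 and 0.694, against 0.729, 0.623 and 0.744 from sharing alone.

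The CD8 signature held 49 probe sets higher and 39 lower in CD8 cells. Its score was -2.12 ± 0.27 (SD, n = 3) in wild-type CD4+CD8- cells and 1.97 ± 0.08 (n = 2) in CD8 cells. Thpok-deficient CD4+CD8- cells scored 0.36 ± 0.22 (n = 3) and Thpok-deficient CD4+CD8+ cells 0.63 ± 0.03 (n = 3). The subsets stood 2.48 and 2.74 above wild-type CD4+CD8- cells, which is 60.7% and 67.1% of the lineage difference. Simulated groups without a change, with noise independent between genes, reached at most 0.62 and 0.63. All 49 probe sets of the higher set were higher and all 39 of the lower set were lower in each Thpok-deficient subset than in wild-type CD4+CD8- cells. These arrays also chose the sets, so the count is not independent evidence of direction. The score of Thpok-deficient CD4+CD8+ cells exceeded that of Thpok-deficient CD4+CD8- cells by 0.26, which did not pass an exact permutation test (two-sided p = 0.2, smallest possible 0.1). Leaving out 1 array, with the signature chosen anew, gave 0.40 without wild-type CD4+CD8- replicate 2, 0.59 and 0.42 without Thpok-deficient CD4+CD8- replicates 1 and 3, and 0.53 without Thpok-deficient CD4+CD8+ replicate 2. It gave 0.40 and 1.70 without CD8 replicates 1 and 2, and a 4-fold list gave 0.61. No exact permutation p could go under 0.1 in any of these settings, so the p-values do not measure stability. Above wild-type CD4+CD8- cells the CD4+CD8+ subset stood at 4.17 with the 4-fold list and at 5.08 without CD8 replicate 2, when the signature held only 3 higher and 5 lower probe sets. These settings also raised the lineage difference, and the share was 69.0% and 66.0%. It was 49.9% without CD8 replicate 1 and 75.5% without wild-type CD4+CD8- replicate 1. For Thpok-deficient CD4+CD8- cells the share was 42.9% and 43.9% without CD8 replicates 1 and 2, and 69.0% without wild-type CD4+CD8- replicate 1. Without Cd4, Cd8a and Cd8b1, the genes of the sort markers, the difference between the subsets was 0.18 (exact permutation p = 0.3). The set higher in CD8 cells did not pass the test between the subsets (camera p = 0.869), and the set lower in CD8 cells was lower in the CD4+CD8+ subset (median -0.16, camera p = 2.45e-05, and p = 0.0777 with an estimated correlation).

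**Figure D4:**
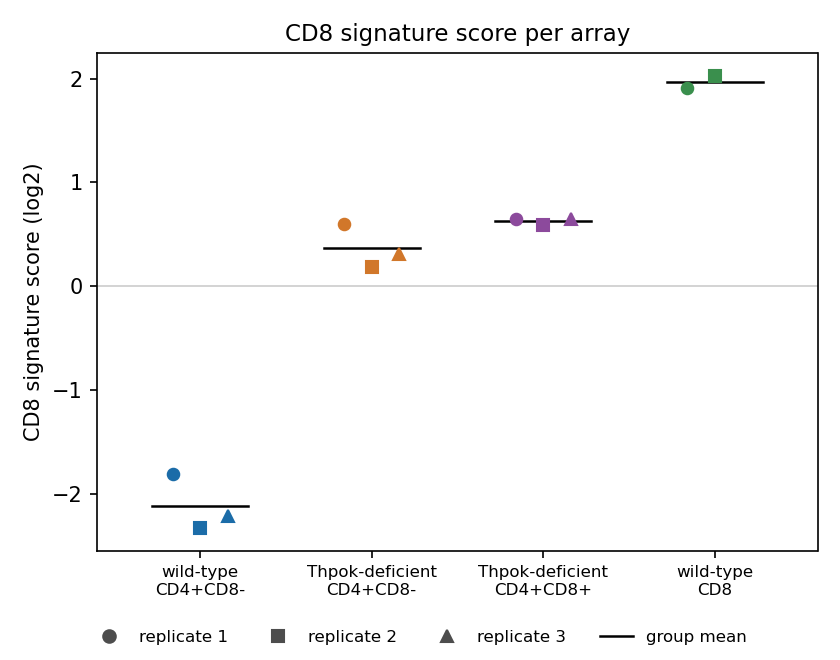
CD8 signature score (log2) of each of the 11 arrays by group, with group means as lines; the score is the mean of the 49 probe sets higher in CD8 cells minus the mean of the 39 lower ones. Both Thpok-deficient subsets (means 0.36 and 0.63) lie between wild-type CD4+CD8- cells (-2.12) and CD8 cells (1.97).

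Thpok-deficient CD4+CD8+ and CD4+CD8- cells were compared directly to find what separates the subsets sorted from Thpok-deficient cells. The CD8 chain genes differed most among the genes always named, with Cd8a at 2.94 ± 0.41 and Cd8b1 at 1.28 ± 0.18 (n = 3 and 3), but neither passed the test (limma adjusted p = 0.188 for each). The arrays of the subsets did not overlap for either gene, which 3 and 3 arrays show by chance in 10% of cases. No probe set was called by limma, while 338 had an unadjusted p under 0.05 (172 higher and 166 lower), and the 9 arrays also called 0, with 557 unadjusted. Other values were -0.91 ± 0.46 for Cd40lg, 0.44 ± 0.55 for Ifng, 0.25 ± 0.28 for Prf1, -0.21 ± 0.25 for Zbtb7b and 0.01 ± 1.10 for Gzmb. Cd4, Runx3, Tbx21, Eomes, Gata3 and Zbtb7a lay between -0.09 and 0.12. The 95% intervals of the model ran from -0.36 to 0.87 for Prf1 and from -2.41 to 2.44 for Gzmb, so a missing call does not show that the subsets are alike. These intervals use the spread shared by all groups. For Gzmb it comes mostly from wild-type CD4+CD8- cells (SD 3.08), which are not compared here. The CD4+CD8- and CD4+CD8+ subsets had SDs of 0.25 and 0.19, so the Gzmb interval overstates their own spread.

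In this comparison 3 of 23 lists shifted, with 0 called members, and none held with an estimated correlation. CD8 lineage genes were higher in the CD4+CD8+ subset in 9 of 11, with 2 adjusted over the list alone (median 0.35, adjusted p = 0.0454, and adjusted p = 0.460 with an estimated correlation). These 2 were Cd8a and Cd8b1, genes of the marker by which the subsets were sorted, so part of this shift was set by the sort. Cytokine receptors were lower in 11 of 15, with 0 adjusted over the list alone (median -0.17, adjusted p = 0.0473, and adjusted p = 0.621 with an estimated correlation), Il18r1 at -0.43 and Ifngr1 at -0.33. B cell markers were higher in 10 of 10, with 0 adjusted over the list alone (median 0.36, adjusted p = 0.0473, and adjusted p = 0.621 with an estimated correlation). Cd79b, a chain of the B cell receptor, stood at 0.80, Cd79a at 0.63 and Cd74 at 0.53. Thpok-deficient CD4+CD8+ replicate 3, an array of narrow range, had the highest mean of the B cell list in the group (5.35), and none of the 3 calls remained on the 9 arrays (adjusted p = 0.0937 for each list). A further quantile normalization gave medians of -0.08 for cytokine receptors and 0.19 for B cell markers, and median centring gave -0.30, 0.23 and, for CD8 lineage genes, 0.21.

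Thpok-deficient CD4+CD8+ cells were compared with wild-type CD8 cells to see how far apart these CD8-bearing effectors stand. Only Cd4 passed the test, higher by 4.95 ± 0.44 in the Thpok-deficient cells (n = 3 and 2, limma adjusted p = 0.00483), and 478 probe sets had an unadjusted p under 0.05. Cd4 is a gene of the sort marker that separates these groups, so its difference was set by the sort. The value of Cd4 on the 9 arrays was 4.94, but it was not called there (adjusted p = 0.119), nor was any other probe set, with 833 at an unadjusted p under 0.05. Cd8b1 stood at -1.61 ± 0.20 (adjusted p = 0.0659), Cd8a at -1.76 ± 0.46, Cd40lg at 1.44 ± 0.51 and Gata3 at 1.15 ± 0.33 (adjusted p = 0.828 for each of the latter 3). Prf1 at -0.50 ± 0.31, Ifng at 0.63 ± 0.62, Tbx21 at 0.52 ± 0.25, Runx3 at -0.42 ± 0.33, Zbtb7b at -0.37 ± 0.28, Gzmb at -0.08 ± 1.23, Eomes at 0.05 ± 0.31 and Zbtb7a at -0.02 ± 0.31 did not pass the test. Without CD8 replicate 2 the count was 0, and without CD8 replicate 1 it was 2.

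CD4 helper genes were higher in the Thpok-deficient CD4+CD8+ cells than in CD8 cells, with Cd4 called and 4 of 11 adjusted over the list alone (median 0.30, adjusted p = 0.00361, and adjusted p = 0.584 with an estimated correlation), Cd5 at 0.95. Cd4 is a gene of a sort marker, so part of this shift was set by the sort, and the list was not tested without it. Glycolysis genes were lower in 8 of 9 with 0 called and 0 adjusted over the list alone (median -0.41, adjusted p = 0.00974, and adjusted p = 0.673 with an estimated correlation), Pfkp at -0.98, Pfkl at -0.79 and Hk2 at -0.67. The helper list had a median of 0.18 with median centring and was not called without CD8 replicate 1 or Thpok-deficient CD4+CD8+ replicate 1, and glycolysis was not called without CD8 replicate 2 or Thpok-deficient CD4+CD8+ replicate 3. Of the CD8 signature, 4 of 49 probe sets of the higher set were positive in this comparison (median -0.49) and 38 of 39 of the lower set (median 0.67). The CD8 arrays also chose these sets, so this is not independent evidence of direction.

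On the 11 arrays some lists did not shift in any of the 5 comparisons. They were the Th2, Th17 and Treg programs, interferon-response and apoptosis genes, and the markers of myeloid, NK, gamma-delta T and erythroid cells. Against wild-type CD4+CD8- cells, in the order of Thpok-deficient CD4+CD8-, Thpok-deficient CD4+CD8+ and CD8 cells, the medians were -0.33, 0.08 and -0.28 for Th2 genes, -0.23, -0.04 and -0.24 for Th17 genes and -0.34, -0.20 and -0.04 for Treg genes. Interferon-response genes had medians of -0.36, -0.04 and -0.44, and apoptosis genes of -0.04, -0.04 and 0.03. On the 9 arrays interferon-response genes were lower in all 3 groups, with medians of -0.16, -0.14 and -0.23 (adjusted p = 0.0150, 0.0143 and 0.0169, and adjusted p = 0.151, 0.184 and 0.160 with an estimated correlation). The cell type markers had medians of -0.32, -0.05 and -0.27 for myeloid cells, -0.22, 0.04 and -0.26 for NK cells, -0.36, 0.0032 and -0.36 for gamma-delta T cells and -0.46, 0.05 and -0.30 for erythroid cells. The list means of gamma-delta T (7.01 and 7.17) and erythroid markers (5.71 and 5.51) were highest in the 2 arrays of narrow range, and B cell markers had medians of -0.29, 0.03 and -0.30 against wild-type CD4+CD8- cells.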

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

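The slopes of the arrays, the test of carried-over CD8-bearing cells, the test of the wild-type CD4+CD8- cultures, the grouping of splits by same-number pairs and every value without the 2 arrays of narrow range were chosen after the result was seen.

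Between the Thpok-deficient subsets, 3 lists passed the list test with a preset correlation. CD8 lineage genes were higher in the CD4+CD8+ subset by a median of 0.35 (adjusted p = 0.0454, and adjusted p = 0.460 with an estimated correlation). That list holds Cd8a and Cd8b1, genes of the sort marker, and was not tested without them. Cytokine receptors had a median of -0.17 and B cell markers of 0.36 (adjusted p = 0.0473 for each, and adjusted p = 0.621 for each with an estimated correlation). The medians were 0.24, -0.05 and 0.18 on the 9 arrays, and no list was called there (adjusted p = 0.0937 for each).

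Replicate 3 of the wild-type CD4+CD8- cells and replicate 3 of the Thpok-deficient CD4+CD8+ cells had slopes of 0.697 and 0.810 on the mean of the other arrays, against 0.960 to 1.03 in the other 9. A narrower signal range fits this, because olfactory receptor genes read high (4.79 and 4.21, against 3.26 to 3.68) and the brightest probe sets read low (a median of 8.62 in the wild-type array, against 9.22 to 9.34). As the whole cause it is excluded for 34 cell cycle and cytotoxic genes of the wild-type array, which lay at a median of -0.90 from that array's own trend, outside the -0.20 to 0.18 of random lists of like signal level. Gzmb lay at -4.56 and Ifng at -1.92 from the trend. A culture with fewer dividing effector cells, another preparation or the quality of the RNA may add to the difference, and the deposited tables cannot tell these apart.

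Thpok-deficient CD4+CD8- cells scored 2.48 above wild-type CD4+CD8- cells on the CD8 signature. Carried-over CD4+CD8+ cells are excluded as the whole source, since Cd8a puts their share at 15.0% or less and Cd8b1 at 33.7% or less, while the median of the other signature genes was at least 86.9% of the change in CD4+CD8+ cells in each array (Prf1 from 54.4% to 108%). The narrow wild-type array is excluded as the whole source, with a difference of 2.12 on the 9 arrays. The choice of the signature on shared arrays gave at most 0.62 in simulated unchanged groups, below the 2.48 seen. Those simulations drew noise independently for each gene. They cannot exclude the choice for arrays whose noise is shared between genes. A difference of the wild-type CD4+CD8- cultures from all other cultures could raise the score of both genotypes at once. The covariance of the changes exceeded that of unchanged groups by 0.115, which this explanation would give as well as an effect of Thpok loss, so it stays open.

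The arrays of each pair of groups with 3 and 3 arrays were also split in all 10 ways. For Thpok-deficient against wild-type CD4+CD8- cells the true split called 14 probe sets and the other splits 0, so 1 of 10 splits reached the true count. For Thpok-deficient CD4+CD8+ against wild-type CD4+CD8- cells it was 2 of 10, with 34 probe sets called at the true split. The other count was 2687, where wild-type replicate 3 stood with Thpok-deficient replicates 2 and 3. That split puts both arrays of narrow range on the same side, but every other split that does so called 0. The position of these arrays alone therefore does not give such a count, and its source was not tested. The other splits that part all 3 same-number pairs, as the true split does, called 0, and with the replicate number as a block the true split called 86. Between the Thpok-deficient subsets every split called 0, so 10 of 10 reached the true count. With 10 splits no share can go under 0.05, and these counts cannot tell chance from a group difference.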

How the results depend on the processing

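No named gene past the threshold changed direction under any alternative, but many of these results could not have reversed. The dim filter, a trended robust prior, no moderation, only the 2 groups and 1 probe set per gene leave the log2 change as it was. Genes picked for no overlap between arrays cannot reverse when arrays are left out or weighted. In 964 results of 62 named calls, 662 were called again and 302 were not. A replicate block, array weights and 1 probe set per gene lost 0 calls, and the dim filter kept 61 of 61. A trended robust prior lost 3, a further quantile normalization 5, the 9 arrays 20, median centring 24, only the 2 groups 49, no moderation 51, and leaving out single arrays 150 of 345. A block and array weights raised the number of calls against wild-type CD4+CD8- cells, so the calls kept under them say little about stability. The weights were 4.27, 0.69 and 0.085 for wild-type CD4+CD8- replicates 1, 2 and 3, so that group then rested mostly on replicate 1. Lists were tested with an estimated correlation, a replicate block, the dim filter, the mean of the probe sets of a gene, the 9 arrays and single arrays left out, and not under the other alternatives. Against wild-type CD4+CD8- cells, CD8 lineage genes were called in all 3 groups under each of these, but not on the 9 arrays with an estimated correlation (adjusted p = 0.106, 0.0799 and 0.0816). That list holds Cd8a and Cd8b1, genes of a sort marker, and was not tested without them. Part of its shift in Thpok-deficient CD4+CD8+ and CD8 cells was therefore set by the sort. For the values below the cause was not tested, except that a stricter threshold lowers a count by construction.

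Genes changed in Thpok-deficient CD4+CD8- against wild-type CD4+CD8- cells (14) were 264 with a replicate block, 40 with the dim filter, 8 with median centring, 0 without moderation, 2078 with array weights, 39 on the 9 arrays, 1 with only the 2 groups, 2 at an adjusted p under 0.01, and 2 to 35 with single arrays left out. For Thpok-deficient CD4+CD8+ cells (34) they were 86 with a block, 146 with quantile normalization, 11 with centring, 5 without moderation, 1987 with array weights, 4 with only the 2 groups, 5 under 0.01, and 4 to 70 with single arrays left out. For CD8 cells (89) they were 240 with quantile normalization, 52 with centring, 27 without moderation, 435 with array weights, 268 on the 9 arrays, 9 with only the 2 groups, 25 under 0.01, and 8 to 129 with single arrays left out. Between the Thpok-deficient subsets (0) they were 1 with a block and 2 with array weights. Between Thpok-deficient CD4+CD8+ and CD8 cells (1) they were 2 with quantile normalization, 0 without moderation, 0 on the 9 arrays, and 0 to 2 with single arrays left out. The cause was not tested.

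Lists shifted, in the same order of comparisons, were 8, 11, 7, 3 and 2, and with an estimated correlation 1, 2, 1, 0 and 0. They were 12 for CD8 cells and 0 between the subsets on the 9 arrays. With a block they were 0 between the subsets and 4 for Thpok-deficient CD4+CD8+ against CD8 cells, where the dim filter also gave 4. A block also ended the call of inhibitory receptors in Thpok-deficient CD4+CD8- cells (adjusted p = 0.0802), where the numbers do not pair the arrays. Between the subsets it ended all 3 list calls (adjusted p = 0.0715 for each). For Thpok-deficient CD4+CD8+ against CD8 cells the lists added by a block were Th1 (median 0.37, adjusted p = 0.000516) and cell cycle genes (0.42, 0.000408), which without the block had adjusted p = 0.673 and 0.899 with an estimated correlation. A block ended no call of a named gene. Single arrays left out gave 5 to 10, 8 to 12, 6 to 12, 1 to 6 and 1 to 3. The cause was not tested.

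The CD8 signature difference between the subsets (0.26) ran from 0.28 to 1.70 with single arrays left out, with the signature chosen anew each time (exact permutation p 0.1 to 0.2). From wild-type CD4+CD8- to Thpok-deficient CD4+CD8+ cells (2.74) it was 4.17 with a 4-fold list, 2.33 on the 9 arrays, and 2.65 to 5.08 with single arrays left out. To Thpok-deficient CD4+CD8- cells (2.48) it was 3.56, 2.12, and 2.37 to 3.38. Shared calls with CD8 cells (12 for Thpok-deficient CD4+CD8- and 28 for CD4+CD8+ cells) and between the subsets (12) were 2, 5 and 2 at an adjusted p under 0.01. They were 39 for Thpok-deficient CD4+CD8- with CD8 cells and 25 between the subsets on the 9 arrays. The cause was not tested.

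Direction reversed only for uncalled genes, and the cause was not tested. In Thpok-deficient CD4+CD8- against wild-type CD4+CD8- cells, Zbtb7a was -0.0520 with quantile normalization, -0.25 with array weights, -0.17 on the 9 arrays, and -0.17 to 0.36 with single arrays left out. In Thpok-deficient CD4+CD8+ cells Zbtb7a was -0.32 with array weights, -0.0952 on the 9 arrays, and -0.0571 to 0.48. In CD8 cells Zbtb7a was -0.11 with weights, -0.0369 on the 9 arrays, and -0.0369 to 0.50, and Tbx21 was -0.0197 with a block, -0.17 with quantile normalization, -0.0558 on the 9 arrays, and -0.29 to 0.33.

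Between the subsets, Zbtb7a was -0.0177 with centring and -0.0698 with weights, and Tbx21 was -0.0281 with centring and -0.0263 to 0.27 with single arrays left out. Gzmb was -0.00492 with quantile normalization, -0.12 with centring, -0.10 with weights, -0.0874 on the 9 arrays, and -0.13 to 0.10. Gata3 was 0.11 with quantile normalization, 0.00613 with weights, 0.0852 on the 9 arrays, and -0.19 to 0.0852. Runx3 was -0.0320 with centring and -0.0344 with weights. Cd4 was -0.00900 with centring, -0.18 with weights, and -0.16 to 0.41. Eomes was 0.0848 with quantile normalization, 0.16 with weights, and -0.33 to 0.16. Against CD8 cells, Zbtb7a was 0.0783 with a block, 0.17 with quantile normalization, and -0.23 to 0.19, and Gzmb was 0.43 with a block and -0.29 to 0.12. Runx3 was -1.0 to 0.15 with single arrays left out, and Eomes was -0.0666 with centring and -0.19 to 0.29. The cause was not tested.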

Other observations

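The lists of metabolic and immediate early genes, their tests and the test of the wild-type CD4+CD8- cultures on cell cycle genes were chosen after the result was seen, as were the values on the 9 arrays.

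Thpok-deficient cells of both subsets and CD8 cells had higher medians for lists of biosynthesis genes than wild-type CD4+CD8- cells, which the fixed lists did not cover. On the 9 arrays, in the order of Thpok-deficient CD4+CD8-, Thpok-deficient CD4+CD8+ and CD8 cells, enzymes of serine and one-carbon metabolism had medians of 0.68, 0.66 and 0.75 (camera p with an estimated correlation 0.0408, 0.0487 and 0.0287). Genes of sterol and fatty acid synthesis had medians of 0.72, 0.99 and 1.23 (0.0329, 0.0471 and 0.0369) and amino acid transporters of 0.86, 0.94 and 1.30 (0.0161, 0.0321 and 0.0351). On all 11 arrays the medians in the same order were 0.77, 0.61 and 0.85 for serine and one-carbon enzymes, 1.36, 1.24 and 1.71 for sterol and fatty acid synthesis and 0.81, 0.89 and 1.15 for amino acid transporters. The list p-values given here are not adjusted and belong to lists picked for their values. Single genes depended on which arrays were used. On all 11 arrays the mitochondrial serine enzyme Shmt2 stood at 1.72, 1.80 and 1.99 (limma adjusted p = 0.0562, 0.0326 and 0.0201), Psat1 at 1.25, 1.09 and 1.62 (0.103, 0.117 and 0.0296) and the leucine transporter Slc7a5 at 1.87, 1.79 and 2.20 (0.0562, 0.0547 and 0.0201), while the desaturase Fads2 (0.124, 0.105 and 0.0865) and the sterol enzyme Lss (0.108, 0.162 and 0.0886) were not called. Without the arrays of narrow range Fads2 stood at 1.70, 1.71 and 1.86 (0.0326, 0.0478 and 0.0138) and Lss at 1.42, 1.32 and 1.41 (0.0326, 0.0474 and 0.0138). Of the other genes, Psat1 was then called in Thpok-deficient CD4+CD8- and CD8 cells (0.0326, 0.0718 and 0.00960), and Shmt2 (0.0777, 0.0807 and 0.0294) and Slc7a5 (0.104, 0.121 and 0.0405) in CD8 cells alone.

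Immediate early genes, which are transcribed within minutes of antigen receptor signalling, leaned higher in the CD4+CD8+ than in the CD4+CD8- Thpok-deficient subset, with 0 of 13 called. On 11 arrays 10 of 13 were positive (median 0.27, unadjusted camera p = 0.0159, and p = 0.207 with an estimated correlation), and on the 9 arrays all 13 were (median 0.33, p = 4.32e-05, and p = 0.0637 with an estimated correlation). Against CD8 cells 9 of 13 were positive on 11 arrays (median 0.26, p = 0.0614 with an estimated correlation) and 12 of 13 on the 9 arrays (median 0.51, p = 0.0285 with an estimated correlation). Between the subsets Egr2 stood at 0.75 and Nr4a1 at 0.63 on 11 arrays (limma adjusted p = 0.683 for each). The list lay at the percentile of 100 among random lists of like signal level, which a list picked for its values would show in any case, so range differences that depend on signal level stay open.

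Cell cycle genes and the 3 metabolic lists had higher medians in Thpok-deficient CD4+CD8- cells than in wild-type CD4+CD8- cells, the cell cycle genes with an adjusted p = 0.194 on 11 arrays and 0.151 on the 9 arrays with an estimated correlation. The narrow wild-type array did not make the whole difference in cell cycle genes. The list means of the lowest arrays of Thpok-deficient CD4+CD8-, Thpok-deficient CD4+CD8+ and CD8 cells still lay 0.35, 0.53 and 0.37 above the highest wild-type CD4+CD8- array on the 9 arrays. The few arrays left can give such gaps by chance, so these gaps alone do not show a difference between the groups. Range differences that depend on signal level are excluded as the whole source for cell cycle genes, which lay at the percentile of 100 among random lists of like level (median 0.98 against an upper bound of 0.23), while for the metabolic lists, also at 100, the test decides nothing because they were picked for their values. Slower growth of the wild-type CD4+CD8- cultures could give the same pattern, and between Thpok-deficient CD4+CD8+ and CD8 cells, without those arrays, cell cycle genes differed by a median of 0.17 (adjusted p = 0.844), 0.24 on the 9 arrays (0.209), 0.26 with quantile normalization and 0.42 with a replicate block (0.000408). With an estimated correlation and no block, the list was not called in that comparison. These medians go with either reading, so whether loss of Thpok or the state of the wild-type cultures raised these genes stays open.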
